A study of Mus musculus with 6 samples.

How the data were processed

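Messenger RNA libraries were made from total RNA of sorted Lgr5-GFP+ cells of mouse small-intestinal crypts with the TruSeq RNA v2 kit after RNeasy Plus Micro extraction, per the labels' protocols. The submitters' processing notes name TopHat, DESeq and the mouse build mm9, without versions. The read counter, the gene annotation, any filter on reads and the use of strand are not given in the sources used here. Groups were taken from the sample titles: 2 WT libraries, 2 RingKO libraries, 1 Bcat library and 1 Bcat_RingKO library.

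The series has 2 tables with 1 line per RefSeq entry. The first covers WT and RingKO (18376 entries, 16820 symbols) and the second the Bcat pair (17076 entries), and 16387 entries are in both. The authors deposited normalized coverage (signal) per entry: group means for WT and RingKO, and 1 value per library for the Bcat pair. From the values, each deposited signal is a read count plus 1, divided by a size factor of its library. The authors deposited a fold (ratio of the group values) and its log2 value for each entry of both tables. The deposited p-values and adjusted p-values of the first table come from the authors' test, with DESeq named by the submitters' processing notes. They equal a Benjamini-Hochberg adjustment over all 18376 entries. Because the first table holds only group means, the test fixed beforehand for that case was used: the authors' deposited adjusted p under 0.05. An authors' mean carries no SD. The authors scaled the 2 tables separately, so levels are compared within a table only. In 29 entries a symbol had been turned into a date, and it was restored through the accession. Of the accessions 98.6% matched the reference annotation (GRCm38), which served for names, gene order and transcript length and GC content. Coordinates are not printed because the files use another build.

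Each group mean is the sum of 2 whole counts with 2 known steps, so the reads of the single libraries were recovered. In WT 18363 values had 1 solution and 13 had more, all at means of 10922 or higher, and in RingKO all 18376 had 1. In the Bcat pair 100% of values were whole within 0.001. In simulated means the recovery returned the right counts for 99.99% of WT entries (2 wrong) and 100% of RingKO entries. The 2 libraries of a group are called A and B. These letters are arbitrary and cannot be matched to the replicate numbers of the labels. The recovered reads gave the depth of each library (922153 to 6753789 reads over all entries), with size factors of 1.56, 1.42, 0.704 and 0.696 in the first table and 0.447 and 2.24 in the second. Entries with reads numbered 16514 and 16092 in WT, 15115 and 15581 in RingKO, 12512 in Bcat and 16757 in Bcat_RingKO, and the 10 largest entries took 1.13% to 5.40% of a library.

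Count tests on the recovered reads were added after the tables had been seen. They were edgeR's quasi-likelihood test with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, DESeq2's Wald test, and limma-trend on log2 values of the recovered normalized reads. Log2 fold changes with SE come from edgeR, the SE being the fold change over the root of its F statistic. They are not used for genes without WT reads, which are given as at least a fold against a floor of 3 reads over the group. This floor is a normalized value of 1.01 in WT, 2.14 in RingKO, 6.71 in Bcat and 1.34 in Bcat_RingKO. The reads of the other group are taken as observed. Such a fold is therefore not a lower confidence limit, and the exact 95% lower limit of the counts lies below it. Genes with 1 to 3 control reads are given as a ratio with an exact conditional binomial (Clopper-Pearson) 95% interval of the counts. Tested on simulated counts for RingKO against WT with 100 genes changed per size, edgeR recovered 67% of 2-fold and 98% of 4-fold changes (8 false calls over 11057 entries). DESeq2 recovered 53% and 95% (2 false of 16032) and limma-trend 68% and 98% (7 false of 10850). The simulated counts had the same dispersion for all entries and both genotypes. In the real libraries the log2 ratio within a group had an SD of 0.225 in WT and 0.428 in RingKO. The simulated shares therefore do not give the power or the false calls of the real comparison.

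Before the data were examined, 32 gene lists (792 genes) were fixed from general knowledge of the tissue, together with the tests, the alternatives and the rule for named genes. That rule takes Ring1, Rnf2, Lgr5, Ascl2, Olfm4, Axin2, Cdkn2a, Zic2 and Zic5 in any case. It adds the 8 largest rises and 8 largest falls past the threshold at a mean of at least 50 with non-overlapping libraries, and up to 4 called members of each list by smallest adjusted p. For the Bcat pair it adds Ctnnb1 and the 8 highest and 8 lowest log2 ratios among genes with at least 50 normalized reads in 1 library. Unnamed predicted genes are skipped. Other genes in the text are marked as chosen after their values were seen. The rule named 91 genes of the first table, and 75 of them passed the threshold. Some genes stand in several lists, such as Ascl2, Axin2, Lgr5 and Sp5 (stem cell and Wnt target), Notum (Wnt target and antagonist), Mmp7 (Wnt target and Paneth), Cdx1 (Wnt target and intestinal identity) and Btg2 (p53 and stress).

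For RingKO against WT each list was tested by a two-sided Mann-Whitney permutation test (100000 permutations) of its deposited log2 fold changes against those of all other entries with a mean of at least 10. The values were adjusted by Benjamini-Hochberg over 30 lists with at least 3 such members. A permutation of genes takes them as independent, so camera with an estimated correlation, camera with a preset correlation of 0.01, and fry were run on the recovered reads. Fry tests whether a list's genes move one way on balance and does not compare a list with other genes. Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of the list's members. For the Bcat pair log2 ratios carry a prior count of 5, entries have a mean of at least 10, no p-value is given, and a list's median is set among 10000 random lists of the same size drawn within 20 expression bins. The comparisons were set side by side by Pearson and Spearman correlation across entries and by the share of called entries with the same sign, with 1000 random sets as reference.

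Alternatives were other thresholds, filters, pseudocounts, prior counts, scalings and tests, and each library left out in turn, which leaves 1 library that is assumed to vary like the other genotype. An edgeR fit without a WT library thus takes its spread from the RingKO pair alone, which differed more. A call lost in such a fit does not show that it depends on the library left out. Alternatives of list tests used 20000 permutations. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.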

Results

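RNA was sequenced from intestinal stem cells sorted on Lgr5-GFP, a reporter of the Wnt co-receptor gene Lgr5, from small-intestinal crypts of C57BL/6 mice 6 days after 3 tamoxifen injections. The 6 libraries fell into 4 groups. WT cells (2 libraries) carried the tamoxifen-activated Cre recombinase alone, and RingKO cells (2 libraries) also carried null alleles of Ring1a (symbol Ring1) and floxed alleles of Ring1b (symbol Rnf2). Ring1 and Rnf2 encode the catalytic subunits of Polycomb repressive complex 1 (PRC1), which places a ubiquitin mark on histones at silent genes. The Bcat and Bcat_RingKO groups (1 library each) carried in addition a Ctnnb1-ex3 allele of the gene for beta-catenin, without and with the Ring alleles. The series asks what part PRC1 plays in keeping the intestinal epithelium in balance. Reads assigned to RefSeq entries came to 6753789 and 6294932 in the WT libraries, 2911422 and 2651201 in RingKO, 922153 in Bcat and 4470853 in Bcat_RingKO. Over 7939 entries with a mean of at least 50 normalized reads, the log2 ratio between the libraries of a group had an SD of 0.225 in WT and 0.428 in RingKO. The squared differences were 6.85 and 13.9 times those that counting noise gives, which does not tell separate animals from technical preparations. The libraries were treated as separate replicates, as their titles number them. The labels do not say that they came from separate animals, and p-values measure only the spread between these libraries, which may be technical. Below, "rose" and "fell" stand for an adjusted p under 0.05 in the authors' deposited table, and a log2 fold change with ± is an edgeR estimate and its SE from the recovered reads of 2 libraries per genotype.

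The targeted genes were examined first. Ring1 fell from 484 and 363 reads in the WT libraries to 9 and 11 reads in RingKO, a log2 fold change of -4.12 ± 0.25. In the authors' deposited table its mean normalized read count went from 283 to 15.7 (adjusted p = 1.26e-26). Ring1 had 24 reads in the Bcat library and 43 in the deeper Bcat_RingKO library, a normalized ratio of 0.358 (95% counting interval 0.213 to 0.617), against 0.0503 (0.0306 to 0.0782) in RingKO. Rnf2 stood at an authors' mean of 158 in WT and 176 in RingKO in the authors' deposited table (adjusted p = 1), and its ratio in the Bcat pair was 1.40 (1.10 to 1.80), or 1.21 with an interval that holds 1 after scaling by trimmed means (TMM). Ctnnb1 had a log2 fold change of -0.20 ± 0.14 in RingKO and a ratio of 1.09 (0.609 to 2.08) in the Bcat pair. The labels do not give the deleted part of Rnf2 or the change in Ctnnb1, and counts over whole transcripts do not check either allele.

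The first comparison asked which genes differ between RingKO and WT stem cells. Among entries with a mean of at least 50 normalized reads, the 8 largest rises were in genes with at most 1 read over both WT libraries: the homeobox and forkhead genes Hoxb13, Esx1, En2, Foxd1 and Hoxd9, the antisense transcript Hoxa11os, and Sim2 and Zic2. Of 37 Hox genes, which pattern the body axis in the embryo, 22 rose over all entries and 26 adjusted over the list alone. Hoxb13, a posterior Hox gene, had no reads in either WT library and 147 and 261 reads in the RingKO libraries, at least 290.2-fold higher against a floor of 3 reads over the WT group. Hoxd9 was at least 119-fold higher, Hoxc6 at least 92.4-fold and Hoxc9 at least 75.2-fold, each from no reads in WT. Hoxa11 and its antisense transcript Hoxa11os were at least 101-fold and 135-fold higher, but overlapping reads of this pair cannot be told apart, since no source states that strand was used in counting. The median log2 fold change of the 27 Hox genes tested as a list was 5.04, or 4.46 with the 13 genes without WT reads set at their bound, and 4.29 over all 37 genes in the table. The two-sided Mann-Whitney permutation test against all other entries gave an adjusted p of 3.33e-05, which 9 lists reached and which stands for 1e-05, the smallest p that 100000 permutations can give. By camera the Hox list had an adjusted p of 0.20 with an estimated correlation and 2.05e-44 with a preset correlation of 0.01, and by fry 0.028. The estimated correlations rest on 2 residual degrees of freedom and are uncertain, for this list and those below.

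Many transcription factors that direct development outside the gut rose as well. Of 111 in the table, 48 rose over all entries, and adjusted over the list alone 53 rose and 1 fell. That 1 was Barx2, chosen after its values were seen (log2 fold change -0.68 ± 0.20). The midbrain and hindbrain factor En2 was at least 149-fold higher, Foxd1 at least 119-fold and the neural factor Zic2 at least 115-fold, as was Esx1, which is outside the list, at least 239-fold, each with no WT reads. Zic5, related to Zic2, was at least 17.8-fold higher. Without WT library A the edgeR quasi-likelihood Benjamini-Hochberg adjusted p of Zic5 was 0.051. Sim2 had 1 read over both WT libraries and was 567-fold higher (95% counting interval 101 to 22472). Barx1, a factor of stomach mesenchyme, had 3 WT reads and was 259-fold higher (88.0 to 1263). The 49 tested factors had a median log2 fold change of 5.18 (5.05 with the 13 without WT reads at their bound) and a permutation adjusted p of 3.33e-05. By camera the adjusted p was 0.20 with an estimated correlation and 3.22e-88 with the preset one, and by fry 0.017. A mean of at least 10 can be reached through the rise itself, and over all 111 factors in the table the median was 2.70. That median carries a shift toward higher values, because an entry without reads stands at 0.672 in WT and 1.43 in RingKO. Their log2 ratio is 1.09. Entries with a mean under 10 had a median deposited log2 fold change of 0.53, against -0.18 at a mean of at least 10. The same shift enters other medians over all genes of a list. The intervals cover counting error only, and a floor covers only that of the group without reads.

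**Figure D1:**
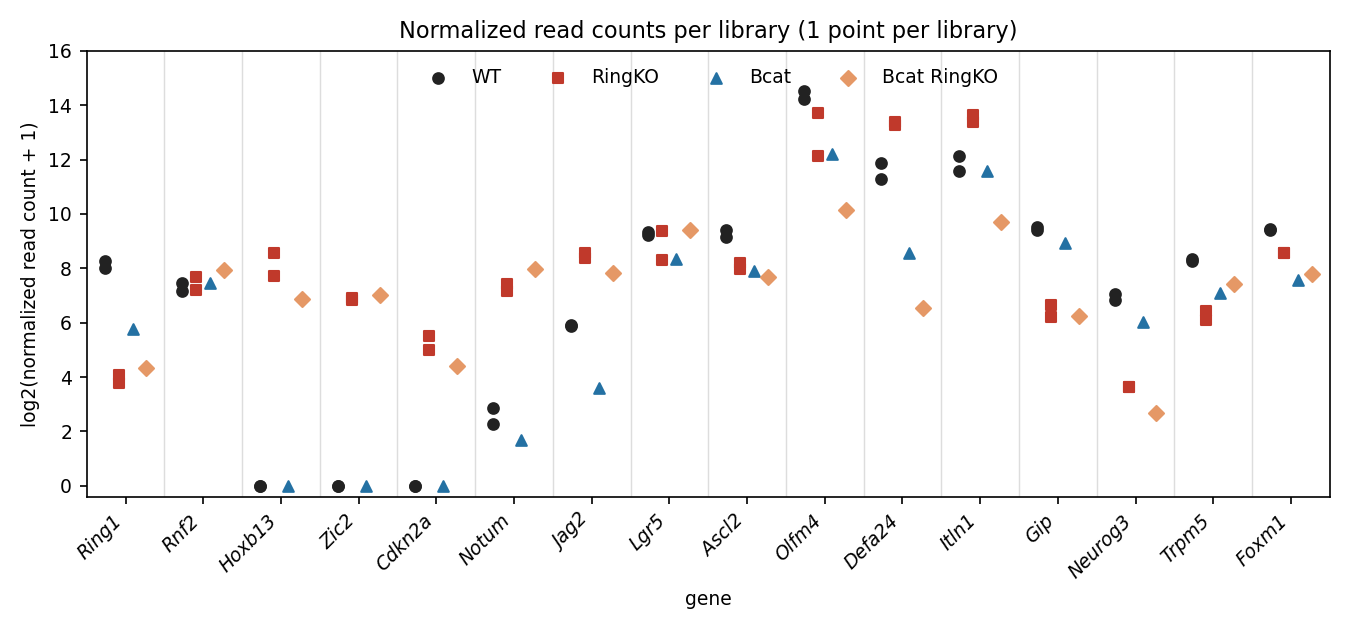
Normalized read count of 16 genes on a log2 axis after adding 1, with 1 point per library and no error bars: 2 WT, 2 RingKO, 1 Bcat and 1 Bcat_RingKO library. Hoxb13, Zic2 and Cdkn2a had no reads in the WT and Bcat libraries, while Defa24 and Itln1 were higher in RingKO than in WT and lower in Bcat_RingKO than in Bcat.

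Among genes of the Polycomb complexes themselves few passed the test. Of 23 PRC1 components 2 rose and 1 fell. Cbx8, which encodes a chromodomain subunit of PRC1, rose with a log2 fold change of 1.21 ± 0.18, and the gene that fell was Ring1. Adjusted over the list alone 3 rose, the added one being Bmi1 (1.43 ± 0.21, chosen after its values were seen). PRC1 components as a list had a median of 0.16, a mean of 0.00 and a permutation adjusted p of 0.0952, which was 0.035 without WT library B and 0.031 without RingKO library B, toward higher values. Of 11 PRC2 components 0 passed the authors' test, 0 adjusted over the list alone, 0 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 0 (median -0.50, adjusted p = 0.143).

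Cdkn2a, a classic Polycomb target that encodes a cell cycle inhibitor and an activator of p53, had no reads in WT and 22 and 31 reads in RingKO, at least 37.7-fold higher. It was the only 1 of 7 cyclin-dependent kinase inhibitors to rise, also adjusted over the list alone, while 3 had an unadjusted p under 0.05, edgeR called 4 as higher and DESeq2 called 2, and the list as a whole did not pass (median 0.61, permutation adjusted p = 0.104; camera with a preset correlation gave 0.048). Of 21 p53 target genes 3 rose, and 3 adjusted over the list alone: Phlda3 (3.01 ± 0.23), Gdf15 (1.40 ± 0.21) and the antiproliferative Btg2. On recovered reads edgeR called 7 p53 targets as higher and DESeq2 called 5. The p53 list had a median of 0.56 (adjusted p = 3.33e-05, and adjusted p = 0.62 with an estimated correlation). Of 33 cell cycle genes 6 fell, and 15 adjusted over the list alone. Foxm1, a regulator of mitotic genes, fell (log2 fold change -0.67 ± 0.13), as did the replication licensing gene Cdt1 (-0.58 ± 0.15), the spindle checkpoint gene Bub1b (-0.63 ± 0.17) and the cyclin gene Ccna2 (-0.60 ± 0.17). The cell cycle median was -0.59 (adjusted p = 3.33e-05, and adjusted p = 0.70 with an estimated correlation). Genes induced by tissue dissociation moved alongside: of 19, 3 rose (Btg2, Dnajb1 at 0.89 ± 0.16 and Jun at 0.95 ± 0.20), 6 adjusted over the list alone, edgeR and DESeq2 each called 12, and their median was 0.81 (adjusted p = 3.33e-05, and adjusted p = 0.62 with an estimated correlation). Their summed normalized reads were 41731 and 51553 in WT and 62213 and 77174 in RingKO. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the calls of Bub1b (adjusted p = 0.052) and Ccna2 (0.060) were lost with all libraries. Without WT library A or B that adjusted p was 0.17 and 0.18 for Foxm1, 0.30 and 0.33 for Cdt1, 0.28 and 0.30 for Bub1b, 0.33 and 0.31 for Ccna2, 0.16 and 0.13 for Dnajb1 and 0.26 and 0.068 for Jun, and without WT library A it was 0.11 for Btg2.

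Stem cell genes were lower in part. Of 36 genes of the Lgr5 stem cell signature, 10 fell and 2 rose, and 14 fell and 3 rose adjusted over the list alone. Ascl2, the transcription factor that sustains Lgr5 stem cell identity, fell (-1.01 ± 0.16), as did the water channel gene Aqp4 (-1.59 ± 0.21), the sodium channel subunit gene Scn2b (-1.56 ± 0.19) and the vitamin D receptor gene Vdr (-0.68 ± 0.16). The 2 that rose were Nrn1 (1.32 ± 0.15) and Nav1 (0.90 ± 0.14), chosen after their values were seen. Lgr5 had a log2 fold change of -0.19 ± 0.27 and did not pass. Olfm4, an abundant stem cell transcript, had 30097 and 33375 reads in WT and 9522 and 3135 in RingKO, a log2 fold change of -1.08 ± 0.42, and did not pass in the authors' deposited table (adjusted p = 0.197). As a list they had a median of -0.50 and an adjusted p of 0.00832, against an adjusted p = 0.77 with an estimated correlation. Without RingKO library B, which held the lower Olfm4 and Lgr5 counts, the list had an adjusted p of 0.37. Without WT library A the edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.073 for Ascl2, 0.18 for Vdr and 0.11 for Nav1, and without WT library B it was 0.32 for Vdr and 0.11 for Nav1.

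Wnt target genes went both ways, with 3 of 26 rising and 3 falling, and 5 and 5 adjusted over the list alone (median 0.01, mean 0.29, permutation adjusted p = 0.582). Notum, which encodes a secreted enzyme that inactivates Wnt ligands, rose (5.09 ± 0.29), as did Cd1d1 (1.95 ± 0.28) and the matrix protease gene Mmp7 (1.32 ± 0.20). The 3 that fell were Ascl2, the caudal homeobox gene Cdx1 and Sp5 (-0.64 ± 0.16, chosen after its values were seen). Axin2, a feedback inhibitor of Wnt signalling, had a log2 fold change of -0.41 ± 0.18 and did not pass in the authors' deposited table (adjusted p = 0.143). Of 13 secreted Wnt antagonists 2 rose and 1 fell, with the same counts adjusted over the list alone: Notum and Sfrp2 (5.14 ± 0.53) rose and Sfrp5 (-1.27 ± 0.25) fell (list median 0.80, permutation adjusted p = 0.0952). Of 17 Notch and lineage regulators 1 rose, and 1 adjusted over the list alone, the Notch ligand gene Jag2 (2.79 ± 0.17). That list had a median of -0.13 but a mean of 0.14 and a permutation test toward higher values (adjusted p = 0.601). The edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.073 for Ascl2 and 0.068 for Sfrp5 without WT library A, 0.057 for Mmp7 without WT library B, and 0.22 and 0.28 for Sp5 without WT library A or B.

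Markers of the differentiated cell types moved in different directions. Of 16 Paneth cell markers 9 rose, and 12 adjusted over the list alone. Paneth cells neighbour the stem cells at the crypt base and secrete antimicrobial peptides, among them the defensins Defa24 (1.90 ± 0.23) and Defa3 (1.90 ± 0.26), which rose with the ribonuclease gene Ang4 (2.60 ± 0.39) and the lectin gene Itln1 (1.81 ± 0.24). Defensin genes are near-identical copies whose reads can be split between them, so their single values are uncertain. Their median was 1.62 (adjusted p = 3.33e-05, and adjusted p = 0.62 with an estimated correlation), and its summed normalized reads were 21193 and 13668 in WT and 45522 and 59515 in RingKO.

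Hormone-producing and tuft cell genes were lower. Of 27 enteroendocrine markers 13 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone. The peptide hormone genes Gcg (-4.43 ± 0.49), Sst (-3.13 ± 0.28) and Gip (-2.84 ± 0.18) fell, as did Neurog3 (-3.23 ± 0.28), the factor that starts enteroendocrine differentiation. The 1 that rose was the hormone gene Sct (2.11 ± 0.20, chosen after its values were seen). Gast, the gene for gastrin, fell (-4.68 ± 0.46), and AI747448 (-3.33 ± 0.19) and the NADPH oxidase gene Nox1 (-3.14 ± 0.27) fell as well. The enteroendocrine list had a median of -2.23, or -1.41 over all its genes in the table (adjusted p = 3.33e-05, and adjusted p = 0.41 with an estimated correlation). Of 18 tuft cell markers 6 fell, and 8 adjusted over the list alone, with a median of -1.52, or -0.95 over all 18 (adjusted p = 3.33e-05, and adjusted p = 0.41 with an estimated correlation). The taste channel gene Trpm5 fell (-1.87 ± 0.18), as did the actin-binding gene Avil (-1.35 ± 0.16), the leukotriene enzyme gene Alox5 (-2.81 ± 0.34) and Rgs13 (-2.13 ± 0.38). For Rgs13 the edgeR quasi-likelihood Benjamini-Hochberg adjusted p was 0.067 and 0.088 without WT library A or B.

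Goblet and absorptive cell genes did not pass as lists with all libraries. Of 16 goblet cell markers 1 rose and 1 fell, and 1 and 2 adjusted over the list alone (median -0.18, permutation adjusted p = 0.974, and 0.030 toward lower values without RingKO library B). Spink4 rose (1.65 ± 0.20) and Retnlb, which encodes a secreted antibacterial protein, fell (-2.16 ± 0.24). The gene added by the list-alone adjustment was Clca3, chosen after its values were seen, with a log2 fold change of -1.28 in the authors' deposited table. Of 28 enterocyte markers 4 fell and 1 rose, with the same counts adjusted over the list alone. Prap1 fell (-1.67 ± 0.26), as did the brush border protease gene Mep1a (-1.52 ± 0.22), the fatty acid carrier gene Fabp2 (-0.96 ± 0.20) and the disaccharidase gene Sis (-0.97 ± 0.23), while the peptidase gene Anpep (0.88 ± 0.15, chosen after its values were seen) rose. The enterocyte list had a median of 0.02 and a mean of -0.12 with a permutation test toward higher values (adjusted p = 0.867), and without RingKO library B it was lower with an adjusted p of 0.0010. The edgeR quasi-likelihood Benjamini-Hochberg adjusted p without WT library A or B was 0.13 and 0.059 for Fabp2, 0.067 and 0.20 for Sis, and 0.15 and 0.13 for Anpep.

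Of 20 transcription factors of intestinal identity 4 fell and 2 rose, and 5 fell and 2 rose adjusted over the list alone (median -0.32, permutation adjusted p = 0.814). Isx, a regulator of vitamin A uptake, fell (-1.12 ± 0.16), as did Hnf4g (-0.84 ± 0.15). Cdx1 (-0.51 ± 0.16) and Hnf4a (-0.43 ± 0.15, chosen after its values were seen) fell in the authors' deposited table, but edgeR's quasi-likelihood test gave them Benjamini-Hochberg adjusted p-values of 0.087 and 0.11. Prdm1, a repressor active in the fetal gut, rose (2.33 ± 0.36), and so did Ihh (0.95 ± 0.14, chosen after its values were seen). Without WT library A or B that edgeR adjusted p was 0.10 and 0.080 for Hnf4g, 0.49 and 0.45 for Cdx1, 0.51 and 0.61 for Hnf4a, and 0.056 and 0.085 for Ihh, and without WT library B it was 0.051 for Prdm1.

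Of 16 squamous and gastric epithelial genes 3 fell, and adjusted over the list alone 3 fell and 2 rose. Gif, the gene for intrinsic factor, fell (-1.68 ± 0.23), as did the pepsinogen gene Pgc (-1.36 ± 0.19) and the gastric mucin gene Muc5ac (-1.27 ± 0.26). The 2 added were Muc6 and Tff2, both higher and chosen after their values were seen, with log2 fold changes of 0.68 and 0.96 in the authors' deposited table. The list had a median of -0.68, or -0.10 over all 16 (adjusted p = 0.0370, and adjusted p = 0.70 with an estimated correlation), and its adjusted p was 0.28 without WT library B and 0.37 without RingKO library B. For Muc5ac the DESeq2 Benjamini-Hochberg adjusted p was 0.052, and the edgeR quasi-likelihood one was 0.058 and 0.20 without WT library A or B. Of 16 germline genes 1 rose, and 1 adjusted over the list alone, the histone reader gene Zcwpw1 (2.89 ± 0.38; list median 0.31, adjusted p = 0.593). Of 20 bile acid and lipid absorption genes 0 passed the authors' test and 0 adjusted over the list alone, while 4 had an unadjusted p under 0.05 and edgeR and DESeq2 each called 3 (median -0.22, adjusted p = 0.903).

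Few genes of the interferon response and of antigen presentation passed, and both lists lay above other entries in the permutation test. Of 21 interferon genes 2 rose, Oasl2 (1.37 ± 0.20) and the antiviral tether gene Bst2 (1.45 ± 0.20), and 3 adjusted over the list alone, the added one being Isg15 (1.98 in the authors' deposited table, chosen after its values were seen). The list had a median of 0.74 (adjusted p = 0.00036, and adjusted p = 0.70 with an estimated correlation). Of 13 genes of MHC class II and antigen presentation 1 rose, the peptide transporter gene Tap2 (0.98 ± 0.14), and 3 adjusted over the list alone, with Psmb8 (0.59) and H2-Aa (0.64 in the authors' deposited table) added and chosen after their values were seen. This list had a median of 0.43 (adjusted p = 0.00608, and adjusted p = 0.70 with an estimated correlation). The edgeR quasi-likelihood Benjamini-Hochberg adjusted p of Tap2 was 0.053 and 0.075 without WT library A or B. Markers of cells that a sort can carry over passed for 1 gene. Of 24 immune cell markers, 10 endothelial markers and 10 glial and neuronal markers 0 each passed the authors' test, 0 adjusted over the list alone, 0 had an unadjusted p under 0.05 and edgeR and DESeq2 called 0. Only 8 immune, 3 endothelial, 3 glial and neuronal and 4 stromal and muscle markers reached a mean of at least 10. The list medians cover these genes alone. Genes with fewer reads could hardly pass, so the lack of calls does not show that such cells were absent. The immune list had a median of -0.02, a mean of 0.11 and a permutation test toward higher values (adjusted p = 0.974), the endothelial list a median of -0.25 (adjusted p = 0.929) and the glial list one of -0.99 (adjusted p = 0.457). Of 14 stromal and muscle markers 1 fell, and 1 adjusted over the list alone, the intermediate filament gene Vim (-1.73 ± 0.19; list median -0.11, mean -0.24, permutation test toward higher values, adjusted p = 0.974). Of the red blood cell genes 2 were in the table at too few reads to be tested as a list, and of 26 mitochondrially encoded genes 0 matched an entry.

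Genes of protein synthesis moved little. Of 46 cytosolic ribosomal protein genes 0 passed the authors' test, 0 adjusted over the list alone and 0 had an unadjusted p under 0.05, while edgeR called 0 and DESeq2 5. Their median of 0.12 lay above that of other entries (adjusted p = 3.33e-05, and adjusted p = 0.82 with an estimated correlation), with an adjusted p of 0.075 without RingKO library A. Of 18 genes of Myc and ribosome biogenesis 0 passed the authors' test, 4 had an unadjusted p under 0.05, edgeR called 1 and DESeq2 0. Adjusted over the list alone 3 fell, Rrp12 (-0.69), Dkc1 (-0.63) and Cad (-0.57 in the authors' deposited table), chosen after their values were seen. This list had a median of -0.35 (adjusted p = 0.0146, and adjusted p = 0.70 with an estimated correlation), with an adjusted p of 0.21 without RingKO library B. Of 10 house-keeping genes 2 fell, and 2 adjusted over the list alone, the respiratory chain gene Sdha (-0.57 ± 0.18) and the glycolysis gene Pgk1 (-0.46 ± 0.16), which the edgeR quasi-likelihood test did not call (Benjamini-Hochberg adjusted p = 0.083 and 0.099). The list had a median of -0.04 and a mean of -0.12 with a permutation test toward higher values (adjusted p = 0.974). For Sdha that edgeR adjusted p was 0.35 and 0.47 without WT library A or B, for Pgk1 0.45 and 0.56, and without RingKO library B it was 0.065 for Pgk1.

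**Figure D2:**
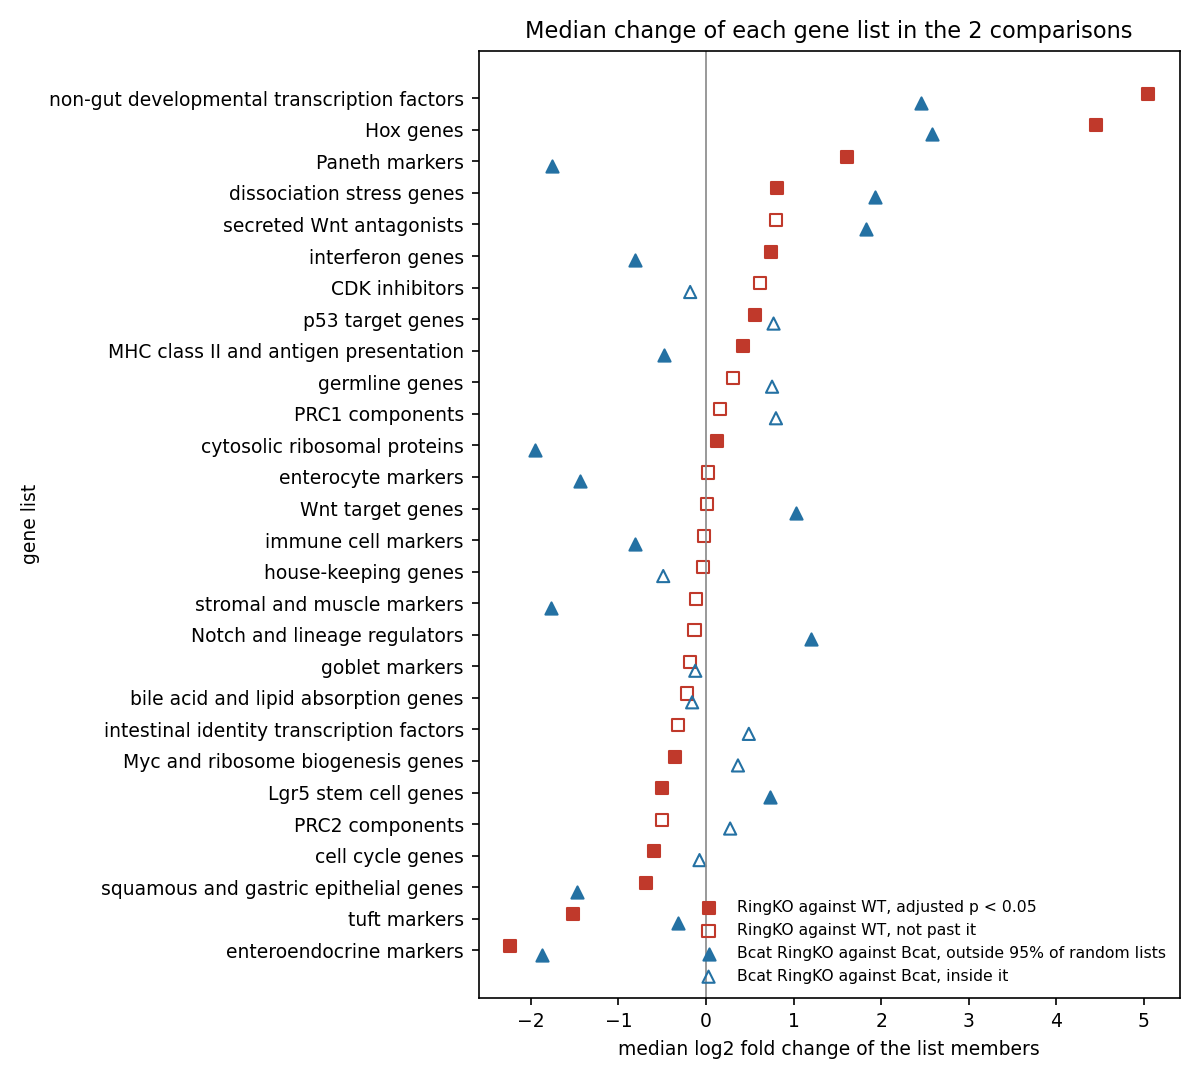
Median log2 fold change (x axis) of 28 gene lists (y axis), squares for RingKO against WT and triangles for Bcat_RingKO against Bcat, with genes without reads in the control set at their bound. Filled squares have an adjusted p under 0.05 and filled triangles lie outside the central 95% of random lists; Hox genes and non-gut transcription factors lie to the right in both comparisons, and Paneth markers at 1.62 and -1.76.

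The authors' deposited table held 18376 entries, of which 900 passed the threshold, 577 higher and 323 lower in RingKO (64.1% higher). Among entries with a mean of at least 50 alone, adjusted anew, 317 were higher and 360 lower. The genes that rose were mostly low in WT: 107 of the 577 had at most 3 WT reads and 85 an authors' mean of at least 100. Of the 323 that fell 283 had an authors' mean of at least 100 in WT. The deposited fold was at least 4 for 376 of the rises and 42 of the falls, with median log2 fold changes of 2.56 and -1.02. On the recovered reads edgeR called 1437 of 11170 tested entries, 1107 higher and 330 lower (77.0% higher), and DESeq2 called 1112 of 12676, 872 higher and 240 lower (78.4% higher). Over the entries edgeR tested, the median log2 fold change was -0.17 in the authors' deposited table and -0.01 by edgeR, so deposited fold changes sit lower by about that difference. The edgeR count was 566 without WT library A (479 higher, 87 lower), 602 without WT library B (519 higher, 83 lower), 3276 without RingKO library A (1938 higher, 1338 lower) and 1911 without RingKO library B (1322 higher, 589 lower). Of the 30 lists tested 14 passed, 8 higher and 6 lower. With an estimated correlation camera called 0 of these lists, with 3 at an unadjusted p under 0.05, and with a preset correlation it called 12 of the 14. Fry called 3, the Hox, non-gut transcription factor and tuft lists.

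The second comparison set the Bcat_RingKO library against the Bcat library, which by their labels share the Ctnnb1-ex3 allele and differ in the Ring alleles. The Ring1 transcript was lower to a smaller degree here than in RingKO, and that of Rnf2 was not lower. With 1 library per group it has no replicate check, and its values describe these 2 libraries. Normalized Xist reads also differed, at 33.5 in Bcat and 935 in Bcat_RingKO. The labels do not give the sex of the animals, so the 2 libraries may differ in more than the Ring alleles. Nes, the gene for the intermediate filament nestin, was at least 34-fold higher from no reads in Bcat, Hoxd4 at least 29.9-fold, the growth factor gene Ptn at least 29.5-fold, the endoderm factor gene Sox17 at least 29.2-fold and the axon guidance receptor gene Robo1 at least 28.6-fold. Barx1, Zic2 and Hoxb13 were at least 19.6-fold, 18.9-fold and 17.3-fold higher and Cdkn2a at least 3.00-fold. The exact 95% lower counting limit was 15.3 for Zic2 and 2.34 for Cdkn2a. Notum had 1 read in Bcat and was 112-fold higher (95% counting interval 20.1 to 4447), Adamts1 also had 1 read and was 95-fold higher (17 to 3760), and Nlgn2 had 3 and was 56.3-fold higher (19.2 to 273). Jag2 and Phlda3 were 20.2-fold (8.62 to 62.6) and 22.8-fold (7.74 to 111) higher. At the other end were the fetal serum protein gene Afp at a ratio of 0.0185 (0.00899 to 0.0343), Rhox8 at 0.0141, Akp3 at 0.0226, Mylk4 at 0.0231, Bst1 at 0.0415, Tmigd1 at 0.0427 and Clca6 at 0.0526. The collagen gene Col1a2 had 25 reads in Bcat and none in Bcat_RingKO, at least 41.7-fold lower. Lgr5 was higher at 2.06 (1.74 to 2.46) and Axin2 at 1.67 (1.49 to 1.87), Ascl2 stood at 0.856 (0.692 to 1.07; 0.737, 0.596 to 0.919, with TMM), and Olfm4 was lower at 0.242 (0.229 to 0.257).

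Of 28 lists described, 17 lay outside the central 95% of 10000 random lists matched on expression. The Hox genes had a median log2 ratio of 3.13 (percentile 100), or 2.59 with genes without Bcat reads at their bound, with 22 of 23 higher. The non-gut transcription factors had one of 3.03 (percentile 100), or 2.46 at the bound, with 39 of 42 higher. Of these members 11 Hox genes and 28 factors had no Bcat reads. They could reach a mean of at least 10 only through Bcat_RingKO, so their direction was fixed by the filter. The random lists were not matched on this. Dissociation stress genes (1.93, percentile 100), secreted Wnt antagonists (1.82, 99.7), Notch and lineage regulators (1.20, 99.8), Wnt targets (1.03, 100) and Lgr5 stem cell genes (0.73, 100) were also high. The ribosomal protein genes lay lowest at -1.96 (percentile 0), with all 43 lower in Bcat_RingKO. Enteroendocrine markers (-1.87), stromal markers (-1.77), Paneth markers (-1.76, with 15 of 15 lower), squamous and gastric genes (-1.47), enterocyte markers (-1.44) and interferon genes (-0.81) were at percentile 0 as well. Immune markers (-0.81, percentile 0.17), MHC class II genes (-0.48, 0.98) and tuft markers (-0.32, 0.55) were low. Inside the central range were PRC1 (0.80, percentile 92.7), p53 targets (0.77, 93.5), germline genes (0.75, 57.8), intestinal transcription factors (0.49, 90.7), Myc genes (0.37, 91.8), PRC2 (0.28, 57.2), cell cycle genes (-0.07, 38.6), goblet markers (-0.12, 53.8), bile acid genes (-0.16, 19.5), CDK inhibitors (-0.18, 11.6) and house-keeping genes (-0.49, 17.9). Among enteroendocrine genes the ratio was 0.154 for Gip, 0.0980 for Sst, 0.0828 for Neurog3 and 0.050 for Gcg. Of 10021 entries with a mean of at least 10, 818 were at least 4-fold higher and 155 at least 4-fold lower, after adding a prior count of 5. The median of all entries was 0.33 with 63.6% higher. TMM scaling moved these to 0.13 and 55.3%, a shift of -0.20.

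Set side by side, the 2 comparisons shared the direction of most genes that rose. Of 505 entries that rose in RingKO and had a mean of at least 10 in both tables, 477 were higher in Bcat_RingKO than in Bcat (94.5%). Over 1000 random sets matched on expression the share was 70.5% on average (central 95% 66.3 to 74.3). A risen gene without Bcat reads reaches that mean only through Bcat_RingKO. Part of this agreement is therefore fixed by the filter, which matching on mean expression does not remove. Of 317 that fell, 196 were lower in Bcat_RingKO (61.8%), against 41.1% (36.0 to 46.7). Hoxb13, Zic2, Notum, Jag2 and Phlda3 were higher in both comparisons and Gip, Gcg, Sst and Neurog3 lower in both, while Defa24 rose in RingKO and stood at a ratio of 0.245 in the Bcat pair. Across 9735 entries the log2 fold changes had a Pearson correlation of 0.551 and a Spearman correlation of 0.398. Genes are not independent replicates, and the comparisons share no library.

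**Figure D3:**
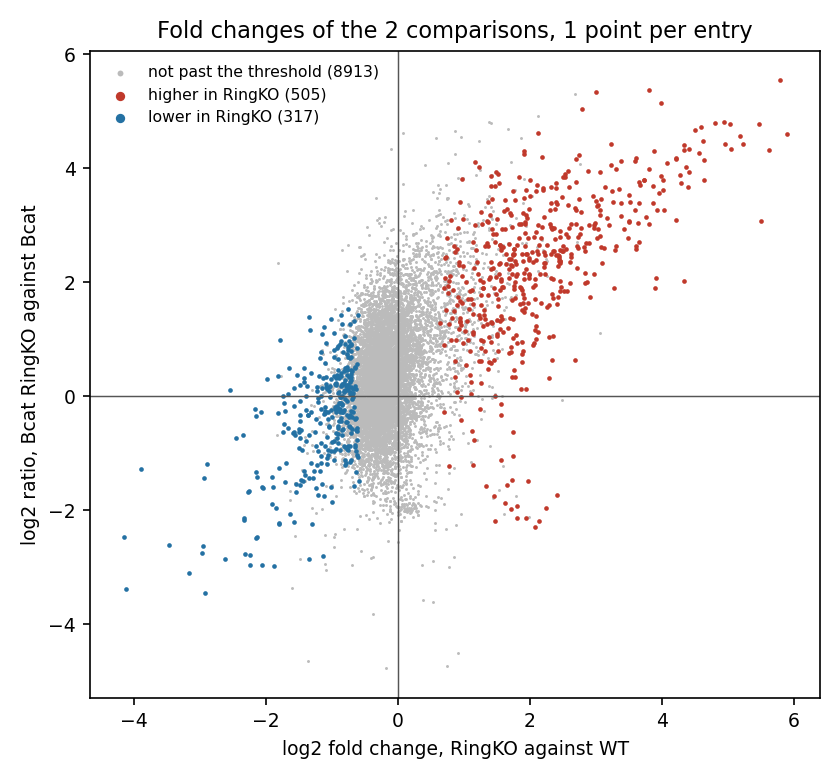
Log2 fold change of RingKO against WT (x axis) and log2 ratio of Bcat_RingKO against Bcat (y axis), 1 point per entry. The 9735 entries have a mean of at least 10 in both tables. Of the colored points, 505 rose and 317 fell in RingKO, and 477 of the 505 lie above 0 on the y axis.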

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

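The test for Paneth cells carried into the sort was chosen, and later revised, after the result was seen, and the one for uniform background reads was added after the other tests had been run but before its own result was known.

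Of the 91 named genes, 11 met 2 conditions together. Both RingKO libraries lay on 1 side of both WT libraries. The Bcat pair went the other way, with a counting interval that excluded 1. Non-overlap by itself held for all 577 entries that rose and all 323 that fell. It held for 51.5% of all entries, where chance gives 33.3% for 2 against 2 libraries. The difference was not tested, since the Bcat pair has 1 library per group. Of these genes 6 are Paneth markers or are made by secretory cells of the crypt: the Bcat_RingKO to Bcat ratio was 0.245 for Defa24, 0.273 for Defa3, 0.272 for Itln1, 0.297 for Ang4, 0.294 for Spink4 and 0.431 for Mmp7, all of which rose in RingKO. The interferon gene Oasl2 rose in RingKO and had a ratio of 0.580 (95% counting interval 0.480 to 0.703) in the Bcat pair. Vim, Cdt1 and Bub1b fell in RingKO and had ratios of 2.03 (1.55 to 2.69), 1.63 (1.28 to 2.10) and 1.22 (1.007 to 1.49). Axin2 was lower in both RingKO libraries without passing the threshold (adjusted p = 0.143 in the authors' deposited table) and had a ratio of 1.67 (1.49 to 1.87). The opposite direction of Bub1b rests on the scaling, since with scaling by trimmed means (TMM) its interval was 0.867 to 1.28, and the median entry of the pair had a log2 ratio of 0.33 as deposited.

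Paneth markers were higher in RingKO than in WT, with a median log2 fold change of 1.62. Transcript length does not account for this: entries of matched length had a median of 0.03, a difference of 1.58 (95% bootstrap 1.42 to 1.75). The bootstrap resampled genes as if independent, so its interval does not cover the spread between libraries. Paneth cells carried into the sort, which the Lgr5-GFP gate should remove, would raise all markers by about 1 factor. The SD of their log2 fold changes (0.558 over 15 genes, range 0.35 to 2.48) was 1.46 times the SE of a single marker (0.382) once the shift that markers share in a library was removed. The test leaves this explanation open: an F test put the spread above error, the ratio stayed below the 2 set against 1 factor, defensin copies share reads, and the WT libraries already held 21193 and 13668 normalized reads of these genes, with Defa24 at 3724 and 2514 against 9788 and 10776 in RingKO. A higher output of Paneth genes by the sorted cells themselves in the RingKO genotype stays open and untested, as does a change in Paneth cell number.

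In the Bcat_RingKO library ribosomal protein genes were lower (median log2 ratio -1.96 over 43 genes) and Hox and developmental transcription factor genes higher than in the Bcat library. The ribosomal protein part lay below entries of matched transcript length by -1.58 (95% bootstrap -1.72 to -1.39) and below entries of matched GC content by -2.35 (-2.46 to -2.21), which argues against either trend as the whole cause. For the Hox and transcription factor part, a uniform background of reads in the Bcat_RingKO library would lift all silent genes alike. The 87 list members with no Bcat read and at most 3 WT reads had a median of 11.2 normalized reads in Bcat_RingKO. This was 12.5 times (5.5 to 20.5) the 0.894 of other silent entries of matched length, which argues against such a background. All bootstrap intervals of this pattern resampled genes as if independent and do not cover differences between single libraries. These entries were not matched on GC content. Across entries GC content correlated with the log2 ratio of the Bcat pair (Spearman 0.315) and with the log2 fold change of RingKO against WT (0.308). A GC trend was thus not tested for the Hox and transcription factor part. An effect of the Ring genotype on the Hox and transcription factor part remains a hypothesis, and for the ribosomal protein genes a difference between single libraries in RNA quality or preparation is untested and confounded with genotype.

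Genes near the targeted loci changed as well, among them Tap2 and Notch3 near Ring1 and Phlda3, Btg2, Nav1 and Rgs13 near Rnf2. Counted outward on either side, the called neighbours nearest Rnf2 were Fam129a (position 1), Ivns1abp (3), Pla2g4a (6), Rgs13 (7) and Rgs2 (8). Phlda3, Nav1 and Btg2 lay at positions 24, 26 and 41. Near Ring1, Tap2 lay at position 10 and Notch3 at 44. Notch3, Fam129a, Ivns1abp, Pla2g4a and Rgs2 were chosen after their values were seen, and a window narrower than 100 neighbours was not tested. DNA carried along with a targeted allele from the strain it was made in could change such neighbours. Among the 100 nearest neighbours of Ring1, 6 were called against 8.19% elsewhere, a ratio of 0.732 (95% interval 0.336 to 1.59, two-sided Fisher exact p = 0.581), and near Rnf2 12 were called against 8.15%, a ratio of 1.47 (0.863 to 2.51, Fisher exact p = 0.195). Both intervals leave room for a moderate excess, and a window of 100 neighbours can dilute one close to a locus. Passenger DNA therefore cannot be told apart from an effect through PRC1 for these genes. Phlda3 and Tap2 were also higher in the Bcat pair, which carries the same Ring alleles and so does not separate the explanations.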

How the results depend on the processing

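For values per library, camera with a preset correlation was planned as the main list test, with camera with an estimated correlation and fry beside it. None of these was planned on recovered reads. All other alternatives that use recovered reads, RLE scaling, a mean of at least 10 for RingKO against WT, TMM scaling of lists or named genes in the Bcat pair, or a left-out library were chosen after the data were seen, and the cause of a change was not tested unless given. No paired analysis was possible because the deposited columns carry no replicate numbers and the recovered libraries cannot be matched to those of the labels. Of the authors' 900 calls (577 higher, 323 lower), an adjusted p under 0.01 kept 622 (182 lower) and an absolute log2 fold change of at least 1 kept 699 (163 lower), as stricter thresholds must. With entries of a mean of at least 50 alone, which are fewer, 677 were called, of which 317 were higher and 360 lower, and with a mean of at least 10, 1010. On recovered reads edgeR called 1437 (1107 higher), DESeq2 1112 (872 higher) and limma-trend 1322, 1393 and 1235 with pseudocounts 1, 5 and 0.1, of which 573, 618 and 524 were lower. The edgeR count was 1441 with RLE scaling and 1375 without a filter, and fell to 760 (652 higher, 108 lower) at an adjusted p under 0.01, and an absolute log2 fold change of at least 1 left 156 lower. Leaving out 1 library moved it from 566 (without WT library A) to 3276 (without RingKO library A), with 479 to 1938 higher and 83 (without WT library B) to 1338 lower, so the edgeR counts depend on single libraries. Rescaling of the deposited group means was not run, because the authors' p-values cannot be recomputed from them. Of the 75 named genes past the threshold, 70 were also called by edgeR, 73 by DESeq2, 55 and 57 without WT library A and B, and 74 and 73 without RingKO library A and B. Of the 14 lists past the threshold, camera with an estimated correlation called 0, camera with a preset correlation 12 and fry 3. The enterocyte list turned lower without RingKO library B (adjusted p = 0.0010), and over all left-out libraries its adjusted p ran from 0.0010 to 0.948. The stem cell list had a permutation adjusted p of 0.056 at a mean of at least 50. Without the filter on low values the MHC class II, ribosomal protein and squamous lists had 0.16, 0.17 and 0.54. Entries with few reads, which the filter removes, carry the upward shift of the added count. Other lists gained a call: PRC1 at a mean of at least 50 (adjusted p = 0.017) and without WT or RingKO library B (0.035 and 0.031), goblet markers without RingKO library B (0.030), and PRC2, secreted Wnt antagonists and germline genes without the filter (0.032, 0.019 and 0.048). Camera with a preset correlation added CDK inhibitors (0.048) and secreted Wnt antagonists (0.00077) and lost the squamous (0.078) and Myc (0.071) lists. In the Bcat pair the 973 entries at least 4-fold apart became 327 (263 higher, 64 lower) with a prior count of 20 and 453 (366 higher, 87 lower) at a mean of at least 50, and TMM scaling gave 235 lower. As a nearly constant shift, TMM moved the stem cell median to 0.52 and the ribosomal protein median to -2.17, and changed whether the counting interval held 1 for 4 of 71 named genes (Ascl2, Bst2, Bub1b and Rnf2). The Hox list median of 3.13 moved to 4.70 with a prior count of 1. The correlation of the comparisons was 0.462 (Spearman 0.304) at a mean of at least 50, 0.823 (0.810) over called entries, 0.613 (0.400) with a prior count of 1, and 0.512 to 0.571 (0.297 to 0.428) with 1 library left out. The share of risen entries with the same sign was 89.1% at a mean of at least 50. Depth limits the Bcat library most: with 922153 reads its floor of 3 reads is 6.71 normalized reads, so a gene absent there shows only a ratio against that floor.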

Other observations

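The genes in this part other than Nes were chosen after their values were seen, and no test beyond those of the report was made. Several genes outside the fixed lists rose in RingKO cells (adjusted p under 0.05 in the authors' deposited table). Mptx1, which encodes a pentraxin of the gut epithelium, rose with a log2 fold change of 6.09 ± 0.19 (edgeR SE), and its relative Mptx2 with 2.26 ± 0.26. The neural progenitor gene Nes rose with 7.08 ± 0.23. The RNA-binding protein genes Igf2bp1 (6.91 ± 0.37) and Igf2bp3 (3.96 ± 0.22), best known from fetal tissue, and the binding protein gene Igfbp2 (2.41 ± 0.30) rose. So did the growth factor gene Igf2, which had no WT reads and was at least 36.9-fold higher. Notch3 (3.80 ± 0.27), Tgfb1 (2.76 ± 0.22) and the lipase and colipase genes Pnliprp2 (2.08 ± 0.29) and Clps (2.02 ± 0.26) rose as well. In the Bcat pair the log2 ratio was 4.78 for Igf2bp1, 2.77 for Igf2bp3 and 3.08 for Mptx1, but -2.29 for Mptx2 and -1.93 for Clps.

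Other genes outside the lists fell in RingKO. The antimicrobial lectin genes Reg3b (-2.80 ± 0.20) and Reg1 (-2.06 ± 0.23) fell, as did Dmbt1 (-1.27 ± 0.23), which encodes a mucosal binding protein, the alcohol dehydrogenase genes Adh1 (-1.52 ± 0.14) and Adh6a (-1.80 ± 0.28), and Spib (-2.37 ± 0.25), a transcription factor of M cells. In the Bcat pair the log2 ratio was -3.44 for Reg3b, -2.97 for Reg1, -1.17 for Adh1 and -1.68 for Spib.

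Every library held reads of Xist, which is transcribed in female cells, and of 4 Y-linked genes. Normalized Xist reads were 198 and 215 in WT and 233 and 202 in RingKO, but 33.5 in Bcat (15 reads) and 935 in Bcat_RingKO (2091 reads). The Y-linked gene Ddx3y had 77.3 and 91.6 normalized reads in WT, 42.6 and 89.0 in RingKO, 69.3 in Bcat and 131 in Bcat_RingKO. A test for cells of both sexes had been planned and was set aside to keep the weighed patterns to 3. The labels do not give the sex of the animals.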
